A study of Nothobranchius furzeri with 20 samples.

How the data were processed

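The 20 libraries were prepared from total RNA of skin of male GRZ fish with a TruSeq RNA kit (version 2), per the labels' protocols, and grouped by the age in the labels, with 5 libraries at each of 5, 7, 10 and 14 weeks. Replicates were numbered in accession order within an age, so the numbers pair no libraries. The labels give no batch, day or family.

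The authors deposited a table of raw counts per gene ID and a table of RPKM values, reads scaled by gene length and library depth. CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 are named in the submitters' processing notes, without settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads from overlapping, antisense or near-identical genes cannot be told apart. None of the 26739 gene IDs was found in the RefSeq gene table of the organism (assembly NfurGRZ-RIMD1), and the files pair no ID with a name. The 45 lists of cell type, tissue and pathway genes fixed before the data were examined were therefore not tested, and no gene symbols are given.

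Counts were analysed as deposited. Genes were kept by edgeR's filterByExpr on the age groups, which left 19192 IDs and 99.89% to 99.98% of each library's counts. edgeR 4.0.16 in R 4.3.3 was used with TMM factors, estimateDisp, glmQLFit and glmQLFTest on a model of 4 group means over all 20 libraries, with 16 residual degrees of freedom, and with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 52.1%. Contrasts were 14 against 5 weeks, each step between neighbouring ages and an F-test over all 4 ages. A second model had age in weeks as a number. The contrasts of 10 with 5 and of 14 with 7 weeks were added after the data were seen. CPM values are counts scaled to a common library size with TMM factors, and log2 CPM used a prior count of 2. The standard error of a log2 fold change is the fold change divided by the square root of its F statistic.

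The rule for named genes, fixed before the data were examined, asked for symbols and otherwise for at most 2 IDs that rose and 2 that fell, with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and no overlap between the libraries of both ages. In the main edgeR fit no ID was called higher at 14 than at 5 weeks. The 2 with the largest rise from 7 to 10 weeks are therefore given, out of 1478 that met the rule there.

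The spread between libraries was the distance of each library from the mean of the other 4 of its age, compared between 14 and 5 weeks by an exact permutation test over 252 splits. Genes on in some libraries and off in others were picked after the data were seen, as those whose second-highest library exceeded 10 CPM and lay over 5 log2 units above the sixth-lowest, on log2(CPM + 0.5), and were grouped by average linkage on 1 minus Pearson's r at a height of 0.3. Their log2 sums were compared between ages by 100000 permutations. The position of a library between the 7 and 10 weeks means is the projection of its log2 CPM on the difference of these means.

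Every pair of libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 48.4, so no library was treated as a second deposit of another. This covers counting error only and cannot tell separate fish from separate preparations of one fish. Library totals of 21581757 to 35137022 counts set the counting precision. The steps were tested on simulated data with 200 changed genes among 19192. Simulated genes varied independently, with the same dispersion at every age. For the real libraries the shares recovered may therefore be too high and the false calls too few. At an adjusted p under 0.05, 62% of genes changed 4-fold and 11% of genes changed 2-fold were recovered between 10 and 7 weeks, with 2 false calls, and 66% and 15% between 14 and 5 weeks, with 2 false calls.

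The deposited RPKM values were compared with the counts before use. Dividing counts by gene length and by each library's own total gave 4.60% of the values, within 0.1% or the last printed decimal. Taking instead a series of 25 depth values that repeats down the rows of the table gave 99.9992% of them. Lengths were recovered with that series, so the first share was bound to lie near the 4.0% of values given their own depth. It is no test of own depths. The ratio of counts to RPKM between 2 libraries needs no length. Grouping rows by their place in the repeat left 1.8e-07 of the variance of its log2 value. Of these 25 depths, 20 matched the totals of the libraries analysed here and 5 matched none of them. The depth used and a library's own depth differed with an SD of 0.288 and a range of −0.79 to 0.70 on the log2 scale. The RPKM table was therefore used only for alternatives, on log2(RPKM + 0.1) with limma 3.58.1 for IDs with an RPKM of at least 0.5 in 5 or more libraries, as deposited and with each library's own depth. Fold changes on that scale understate changes of low genes. The same comparison gave a length for 19638 IDs, with a median of 2472 bases.

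Alternatives fixed before the data were examined were RLE and upper-quartile factors, no filter and a filter of at least 5 CPM in 5 or more libraries, DESeq2 1.42.0, limma voom, a robust edgeR fit, the RPKM table, fits on the 2 ages alone, other scales of age, other measures of spread and leaving out each library in turn. Chosen after the data were seen were leaving out 9 libraries with a set of on/off genes over 1000 CPM, the log2 sums of these sets as covariates, leaving out 5 weeks replicates 4 and 5, counts thinned to the smallest library (for the spread between libraries this was fixed before), an offset for gene length, RPKM with each library's own depth, and counting only genes outside the sets. Calls were also counted over 100 splits of the libraries per comparison. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the RPKM check and the plots.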

Results

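Skin of male turquoise killifish (Nothobranchius furzeri) of the inbred, short-lived GRZ strain was profiled by RNA-seq at 4 ages, 5, 7, 10 and 14 weeks, with 5 libraries per age. The series title sets the question as how skin expression differs between age groups. Library totals ran from 24747312 to 35137022 counts at 5 weeks, from 22069927 to 29724151 at 7 weeks, from 21616172 to 32418365 at 10 weeks and from 21581757 to 33838693 at 14 weeks. Of 26739 gene IDs, 19192 had enough counts to be tested. The labels do not say whether the libraries came from separate fish, so p-values measure the spread between these libraries, part of which can be technical. The sample titles carry a different number for each library, without saying what it stands for. The files name genes by ID only and no ID matched the table of gene names, so genes are described here by their age profiles and by groups of co-varying genes, without function.

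The 20 libraries did not order by age along the main axis of variation. The first principal component of log2 CPM (counts scaled to a common library size) held 42.8% of the variance and set 4 libraries far to one side, 7 weeks replicate 3 at 85.4, 10 weeks replicate 4 at 118.2, 14 weeks replicate 3 at 151.2 and 14 weeks replicate 4 at 189. The second component, with 17.6% of the variance, placed all 5 libraries of 7 weeks and replicates 1, 2 and 3 of 5 weeks below 0. All 5 libraries of 10 weeks, replicates 4 and 5 of 5 weeks and replicates 1, 2 and 5 of 14 weeks lay above 0. Each library of 5 and 7 weeks had its nearest neighbour, by Spearman's rho across genes, at its own age, against 1 of 5 libraries at 10 weeks and 2 of 5 at 14 weeks. At 5 weeks, replicates 4 and 5 were nearest to each other (0.956) and reached at most 0.94 with replicates 1 to 3. Replicate 4 had a rho of 0.954 with 10 weeks replicate 5. Replicate 5 had one of 0.955 with 14 weeks replicate 5.

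**Figure D1:**
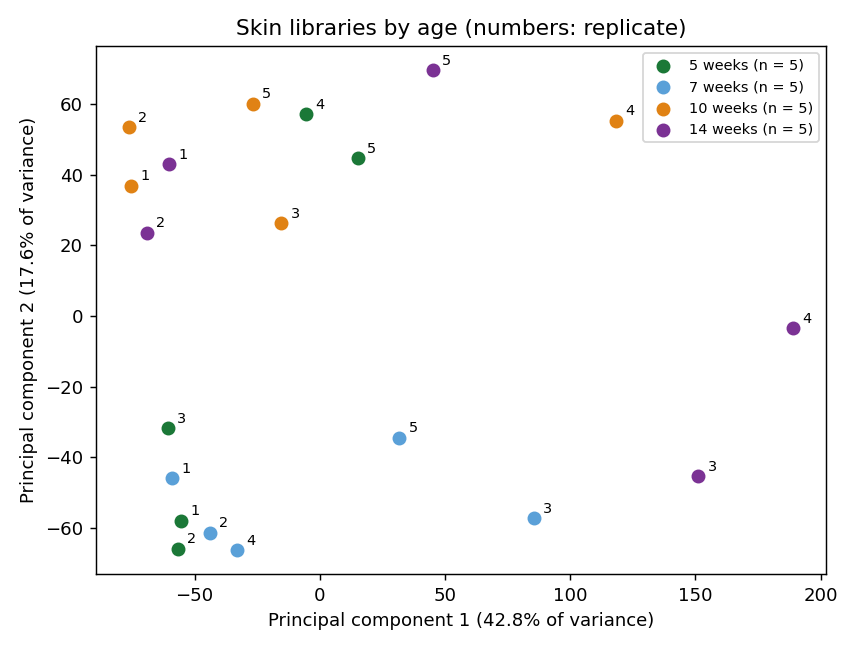
Principal components 1 (x axis, 42.8% of variance) and 2 (y axis, 17.6% of variance) of log2 CPM over 19192 genes, with 1 point per library, coloured by age and numbered by replicate. The libraries of 7 weeks lie below 0 on component 2 and those of 10 weeks above 0, while 5 weeks replicates 4 and 5 lie with the 10 weeks libraries at 57.1 and 44.7.

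Over the 4 ages together, 5000 genes (26.1% of those tested) differed in edgeR's quasi-likelihood F-test at an adjusted p under 0.05. In 72.5% of them the highest or the lowest of the 4 age means fell at 7 weeks, against 58.4% of all tested genes. The most frequent profile, 1279 genes (25.6%), had its highest mean at 7 weeks and its lowest at 10 weeks. The mirror profile, lowest at 7 and highest at 10 weeks, held 971 genes (19.4%). A further 662 genes (13.2%) had their lowest mean at 5 weeks and their highest at 14 weeks. Means that increased at every step were found in 253 genes, 5.06% of the 5000 against 4.36% of all tested genes. Means that decreased at every step were found in 61, 1.22% against 3.44%. The count of 5000 fell to 3082 without 7 weeks replicate 2 and to 3131 without 7 weeks replicate 4, and DESeq2 called 7563 genes. Of 100 splits of the libraries over the ages, only the real one reached 5000. The highest other called 4424, so chance was not firmly excluded.

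The largest difference between neighbouring ages lay between 7 and 10 weeks. At 10 weeks 2009 genes were higher and 2423 lower than at 7 weeks, together 23.1% of those tested, and 1084 and 1328 of these changed at least 2-fold. The median size of the change among the called genes was 1.05 on the log2 scale. With 5 libraries per age, 1776 genes were higher and 2330 lower in every 10 weeks library than in every 7 weeks library. That was 21.4% of the tested genes, where chance gives 0.79% on average. Genes vary together, so a given split of libraries can lie far from that average. Of the comparisons chosen after the data were seen, that of 14 with 7 weeks called 1802 genes higher and 1566 lower, and that of 10 with 5 weeks called 1268 genes, 456 higher and 812 lower. The RPKM table, whose values carry a depth error described with the processing, called 1763 genes in limma.

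Of the genes that rose from 7 to 10 weeks with no overlap between the libraries of both ages, the largest fitted rise was that of Nfu_g_1_001708. Its level was 1.6 ± 1.01 CPM (SD, n = 5) at 7 weeks and 205 ± 126 CPM (SD, n = 5) at 10 weeks, a log2 fold change of 6.99 (SE 1.62; adjusted p = 0.00499, edgeR). Nfu_g_1_001750 followed, from 0.155 ± 0.153 CPM (SD, n = 5) to 15.7 ± 7.34 CPM (SD, n = 5), with a log2 fold change of 6.55 (SE 1.66; adjusted p = 0.00856, edgeR). Neither level was uniform at the other ages. At 5 weeks Nfu_g_1_001708 ranged from 1.24 to 165 CPM and at 14 weeks from 5.69 to 748 CPM. Nfu_g_1_001750 ranged from 0.0389 to 6.56 CPM at 5 weeks and stood at 7.5 ± 15.7 CPM (SD, n = 5) at 14 weeks.

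**Figure D2:**
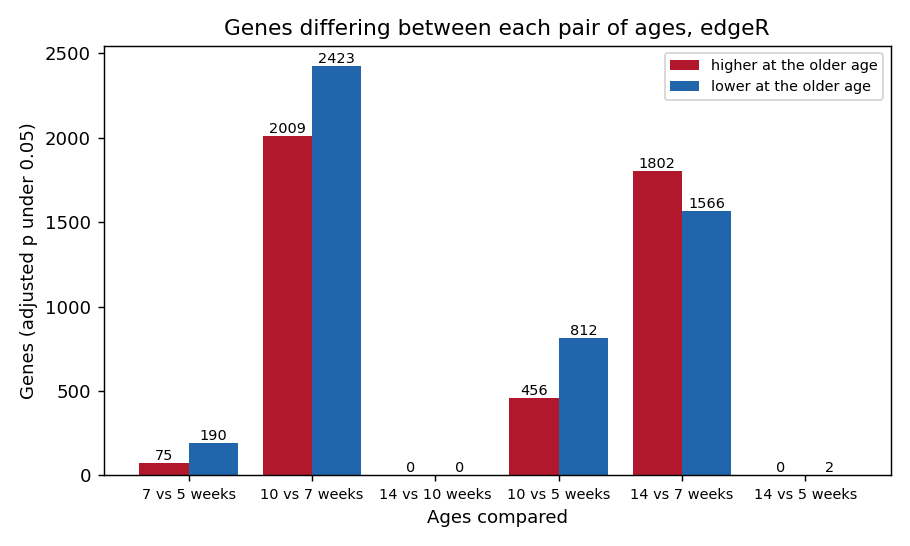
Number of genes (y axis) with an adjusted p under 0.05 in edgeR for each pair of ages (x axis), with red bars for genes higher and blue bars for genes lower at the older age; n = 5 libraries per age. The pair of 10 and 7 weeks has 2009 and 2423 genes, and the pair of 14 and 10 weeks has 0.

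From 5 to 7 weeks, 75 genes were higher and 190 lower at 7 weeks (265 in all, 1.38% of those tested), with 44.9% of them changed at least 2-fold. In every 7 weeks library, 675 genes were higher and 801 lower than in every 5 weeks library. That was 7.69% of the tested genes, where chance gives 0.79% on average. Of the 190 lower at 7 weeks, 160 were called higher at 10 weeks, and of the 75 higher at 7 weeks, 48 were called lower at 10 weeks, where independent lists would share 19.9 and 9.47. No gene was called in the same direction at both steps, where independent lists would share 7.85 and 24. Both comparisons use the 7 weeks libraries, which alone links them with opposite signs. The covariance of the 2 sets of fold changes across genes was −0.253, against −0.142 on average (−0.152 to −0.135) in 20 simulated data sets with unchanged groups, a difference of −0.112 before rounding. The correlation was −0.55, against −0.5 (−0.53 to −0.49) in the simulated sets. Simulated genes varied independently of each other, with the same dispersion at all ages, while genes of the real libraries vary together. The simulated ranges may therefore be too narrow, and the comparison does not decide whether the reversal exceeds chance. With the 7 weeks libraries split between the comparisons the covariance was −0.164 on average over 10 splits, from −0.211 to −0.059.

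The count of 265 genes rested on single libraries of both ages. It was 51, 27, 160 and 19 without 7 weeks replicate 1, 2, 3 and 4, 66, 31 and 44 without 5 weeks replicate 3, 4 and 5, and 173 without 10 weeks replicate 5. It reached 323 at most on leaving out 1 library, and DESeq2 called 1121, 523 higher and 598 lower. With only the 2 ages fitted, 141 were higher and 194 lower. Replicates 4 and 5 of 5 weeks stood apart from replicates 1, 2 and 3. A scale over the 4432 genes that differed between 10 and 7 weeks, set to 0% at the 7 weeks mean and 100% at the 10 weeks mean, placed replicates 1, 2 and 3 at 12.6%, 3.03% and 29.3%. Replicates 4 and 5 stood at 77.3% and 68.0%. The 14 weeks libraries stood at 104%, 80.8%, 43.4%, 45.6% and 78.4%. The means at 0% and 100% came from the 7 and 10 weeks libraries alone. The genes were chosen on the difference between these 2 ages in the fit of all 20 libraries. Those of 5 and 14 weeks thus entered the choice through the filter, the TMM factors and the shared dispersion. The scale therefore compares libraries within an age, and a distance from 0% or 100% is not a test. Replicates 4 and 5 were also the 5 weeks libraries in which 164 co-varying genes (set 2 of those given with the sets of genes) were abundant, at 7850 and 17100 CPM in sum against 90.4 to 94 CPM in replicates 1 to 3. With replicates 4 and 5 of 5 weeks left out, an alternative chosen after the data were seen, 2 genes were called between 7 and 5 weeks and 1478 between 14 and 5 weeks. The labels hold nothing against which the age given for these 2 libraries can be checked, so a wrong label is not excluded, and the 5 weeks means and counts are subject to that limit.

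**Figure D3:**
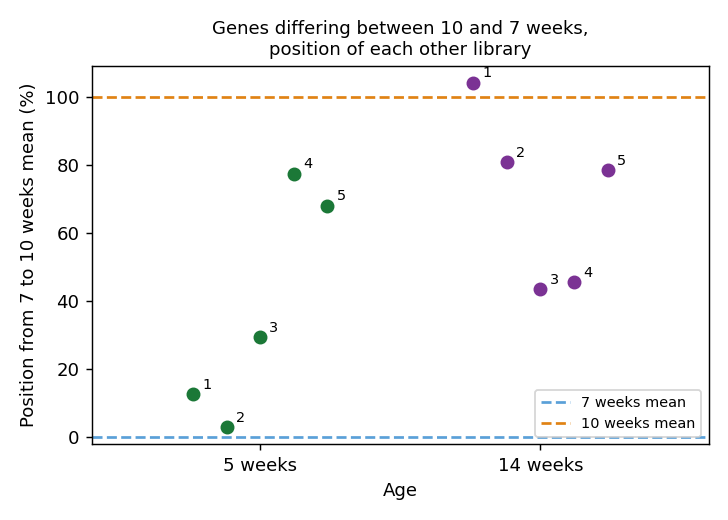
Position of each 5 and 14 weeks library (x axis, numbered by replicate) between the 7 weeks mean (0%, lower dashed line) and the 10 weeks mean (100%, upper dashed line) on the y axis, over 4432 genes that differed between 10 and 7 weeks. The 5 weeks libraries 4 and 5 stand at 77.3% and 68.0%, and the other 5 weeks libraries at 29.3% or below.

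Between 10 and 14 weeks no gene passed the adjusted threshold in edgeR, with a smallest adjusted p of 0.202, and 3598 genes (18.7%) had an unadjusted p under 0.05. limma voom called 0 genes and DESeq2 called 244, of which 189 were higher and 55 lower at 14 weeks. In 84 genes every 14 weeks library was above every 10 weeks library and in 75 every one was below. That was 0.828% of the tested genes, where chance gives 0.79% on average. Without 14 weeks replicate 1, 514 genes passed. In simulated counts this comparison recovered 62% of genes changed 4-fold and 9% of genes changed 2-fold. The simulation took the dispersions of these data and 200 changed genes, and the shares hold for that number. Its genes varied independently, with the same dispersion at all ages. The real libraries of 14 weeks were more spread than those of the other ages, so these shares may be too high here.

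The oldest and the youngest group, 14 and 5 weeks, differed in 2 genes, both lower at 14 weeks, while 4517 genes (23.5%) had an unadjusted p under 0.05. In 275 genes every 14 weeks library was above every 5 weeks library and in 151 every one was below. That was 2.22% of the tested genes, where chance gives 0.79% on average. Genes vary together, so a given split can lie far from that average, and whether 2.22% exceeds chance was not tested. Nfu_g_1_022937 fell from 5.77 ± 6.21 CPM (SD, n = 5) to 0.0703 ± 0.0677 CPM (SD, n = 5), a log2 fold change of −6.19 (SE 0.87; adjusted p = 0.0206, edgeR). Its level at 7 weeks was 1.28 ± 0.404 CPM and at 10 weeks 0.289 ± 0.172 CPM (SD, n = 5 each). Nfu_g_1_023228 fell from 5.09 ± 6.58 CPM (SD, n = 5) to 0.0708 ± 0.0621 CPM (SD, n = 5), a log2 fold change of −6.01 (SE 0.91; adjusted p = 0.0262, edgeR), with 0.856 ± 0.204 CPM at 7 weeks and 0.138 ± 0.11 CPM at 10 weeks (SD, n = 5 each). Both were also among the genes lower at 10 than at 7 weeks. Both 5 weeks means were raised by replicate 2, at 16.4 and 16.6 CPM, without which the log2 fold changes were −5.36 and −4.87 (adjusted p = 0.0207 for both, edgeR). At 14 weeks they rested on 0 to 5 and 0 to 6 counts per library. Neither passed in limma voom, where the adjusted p was 0.0887 for both, nor in edgeR on the 2 ages alone, where it was 0.209 for both.

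The number of genes called between 14 and 5 weeks rested on single libraries. It was 1498, 2141 and 1284 without 14 weeks replicate 1, 2 and 5, 0 without 14 weeks replicate 3 or 4, 114 and 58 without 5 weeks replicate 4 and 5, and 1 without 7 weeks replicate 5. DESeq2 called 2305 genes, 1788 higher and 517 lower, and without 14 weeks replicate 1, 2 and 5 the genes higher at 14 weeks numbered 1238, 1593 and 1103. Lower genes were the more frequent in other settings, with 36 higher and 78 lower without 5 weeks replicate 4 and 21 higher and 37 lower without 5 weeks replicate 5. The same held in alternatives chosen after the data were seen, with 676 higher and 802 lower without both of these libraries and 1087 higher and 1422 lower without the 9 libraries with a set of co-varying genes over 1000 CPM.

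**Figure D4:**
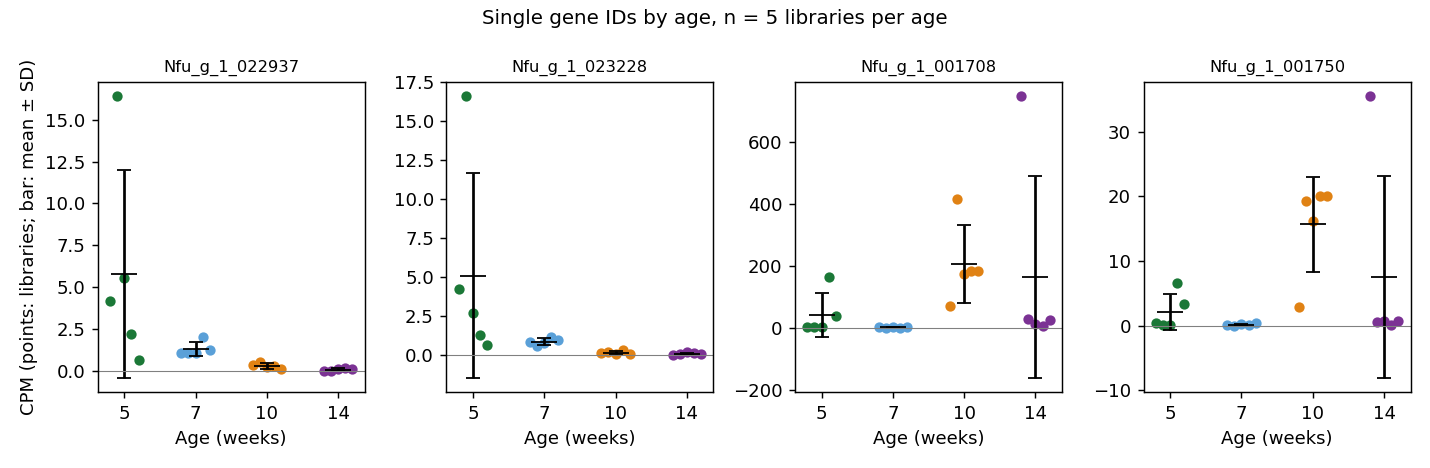
CPM (y axis, own scale per panel) of the 4 named gene IDs by age in weeks (x axis), with 1 point per library and the mean ± SD of 5 libraries as a bar. Nfu_g_1_022937 and Nfu_g_1_023228 have means of 5.77 and 5.09 CPM at 5 weeks and of 0.0703 and 0.0708 CPM at 14 weeks, and Nfu_g_1_001708 and Nfu_g_1_001750 are each above their 7 weeks levels in all 10 weeks libraries.

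A linear trend over age in weeks was called for 1306 genes in edgeR, 827 rising and 479 falling, with a median absolute slope of 0.15 log2 units per week, and 1147 of them were also among the 5000 genes above. With upper-quartile factors the split was 567 rising and 668 falling. The count was moved by more than 1.5 times by leaving out any of 14 libraries, from 7 genes without 5 weeks replicate 1 to 2867 without 14 weeks replicate 2.

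Some genes differed strongly between libraries, a pattern found after the data were seen. By a rule on a gap of over 5 log2 units between libraries, 377 such genes were picked, and 375 of them fell into 3 sets of 181, 164 and 30 genes. Within a set, the median Pearson's r between genes across libraries was 0.98, 0.96 and 0.97, which grouping by this r favours. Between genes of different sets the median r was 0.46 for sets 1 and 2, 0.39 for sets 1 and 3 and 0.56 for sets 2 and 3. Set 1 summed to 20800 CPM in 14 weeks replicate 3, 12900 CPM in 14 weeks replicate 4 and 105 CPM in its lowest library. Set 2 reached 55400 CPM, or 5.54% of the counts, in 14 weeks replicate 4, 35900 CPM in 14 weeks replicate 5, 34200 CPM in 10 weeks replicate 4 and 17100 CPM in 5 weeks replicate 5, with 90.4 CPM in its lowest library. Set 3 reached 20500 CPM in 10 weeks replicate 4 and 13300 CPM in 14 weeks replicate 4.

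These sets were over 1000 CPM in 5, 9 and 3 of the 20 libraries. Set 2 was so at every age, in 2, 2, 2 and 3 of 5 libraries from 5 to 14 weeks. Set 1 was so in 0, 2, 1 and 2 of 5 libraries, and set 3 in 1, 0, 1 and 1. No set differed between ages beyond the spread between libraries, in permutation tests of the log2 sums over 4 ages (p = 0.361, 0.734 and 0.671, each 0.734 after adjustment over the 3 sets). Of the 181 genes of set 1, 135 were among the 5000 called over the 4 ages, against 26.1% of all tested genes. None was called between 14 and 5 or between 10 and 7 weeks. The F-test takes the same dispersion at every age. The log2 sum of set 1 had an SD of 0.26 at 5 weeks and 3.57 at 14 weeks (n = 5 each). These calls may reflect unequal spread as well as age means, which was not tested. In 9 libraries any set was over 1000 CPM, 2, 2, 2 and 3 from 5 to 14 weeks, with 5 weeks replicates 4 and 5 among them. Without these 9, edgeR called 5811 genes between 10 and 7 weeks and 2509 between 14 and 5 weeks. It called 1 between 7 and 5 weeks and 0 between 14 and 10 weeks, where 524 had an unadjusted p under 0.05. This fit rests on few libraries per age, left after a choice made on the same data. With all 20 libraries and the log2 set sums as covariates the counts were, in that order, 5125, 5, 540 and 0. The 2 settings thus disagree on 14 against 5 and on 7 against 5 weeks.

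**Figure D5:**
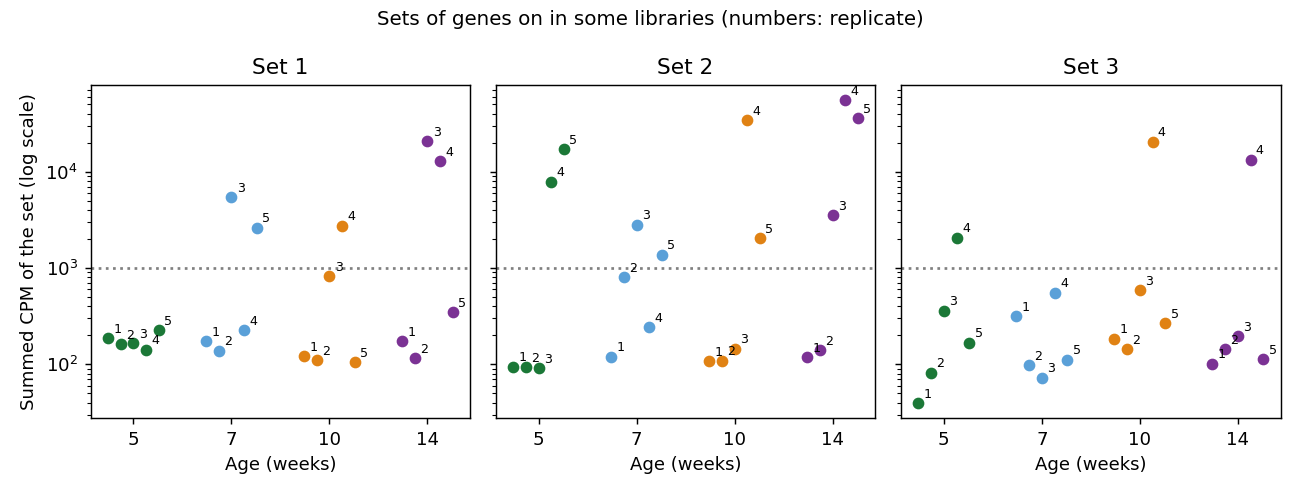
Summed CPM (y axis, log scale) of the 3 sets of genes in each library by age in weeks (x axis), with 1 point per library numbered by replicate and a dotted line at 1000 CPM. Set 2 spans 90.4 to 55400 CPM and lies above the line in 9 libraries.

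Libraries of 14 weeks differed more from each other than those of 5 weeks. The distance of a library from the mean of the other 4 of its age, as 1 minus Spearman's rho, averaged 0.109 ± 0.037 (SD, n = 5) at 14 weeks and 0.038 ± 0.0196 (SD, n = 5) at 5 weeks. The difference of 0.0714 gave p = 0.00794 in a two-sided exact permutation test, the smallest p that 5 against 5 allow. The averages at 7 and 10 weeks were 0.035 ± 0.017 and 0.0456 ± 0.0436 (SD, n = 5 each). Distances within a group share libraries and are not independent of each other, which the test leaves out. Over genes outside the 3 sets the difference was 0.0538, with p = 0.00794 in the same exact test. Without the 9 libraries with a set over 1000 CPM it was 0.0285, with p = 0.1 in the exact test, the smallest that 2 against 3 libraries allow. There each 14 weeks library was set against the only other one of its age, and each 5 weeks library against the mean of 2. The measure was thus not alike at both ages, which alone can raise the 14 weeks distance.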

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

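The tests of the on/off gene sets against age, those of the difference between 10 and 7 weeks and those of the RPKM table were chosen after the result was seen, while the slope test and the counts over other splits were set before. The slope value and the count of splits for 0 genes were taken as deciding nothing only after they were seen. Dixon's test for an outlier, at its critical value of 0.71 for 5 values, was run on 12 measures in 4 ages, 48 groups of 5 libraries. It picked 7 values where chance gives 2.4. The measures include the sums of the on/off sets and the named IDs, which were selected on these same libraries. That selection can favour an excess over 2.4. The distance of 7 weeks replicate 3 from the other libraries of its age was 0.0649, against 0.0236 to 0.0313 for the others. That of 10 weeks replicate 4 was 0.123, against 0.0189 to 0.0309. The log2 summed CPM of set 3 was 14.3 in 10 weeks replicate 4, against 7.16 to 9.21, and 13.7 in 14 weeks replicate 4, against 6.66 to 7.61. The log2(CPM + 0.5) of Nfu_g_1_022937 was 1.32 in 7 weeks replicate 4, against 0.634 to 0.812. That of Nfu_g_1_001750 was 1.74 in 10 weeks replicate 1, against 4.06 to 4.36, and 5.17 in 14 weeks replicate 1, against −0.62 to 0.183.

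Of the genes on in some libraries and off in others, age was not the whole cause of set 2. Libraries with set 2 over and under 1000 CPM occurred at 4 of 4 ages. Sets 1 and 3 were not in this test. Set 1 was over 1000 CPM in 0, 2, 1 and 2 of 5 libraries from 5 to 14 weeks, and set 3 in 1, 0, 1 and 1. A source of RNA that enters libraries in different amounts, such as tissue other than skin taken with the sample, predicts that the genes of a set rise in proportion, and 92.5% of the 345 genes of sets 1 and 2 had a slope between 0.8 and the inverse of 0.8 on the rest of their set, over libraries above 1000 CPM. This value decides nothing, because picking and grouping the genes by their gap and correlation favours such slopes, genes regulated together in the skin may rise in proportion too, and without gene names no tissue can be assigned. An effect of age on how often such libraries occur stays open and untested beyond the permutation tests.

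The difference between 10 and 7 weeks was not accounted for by depth, with 4393 genes called after thinning against 4432. It was not accounted for by gene length, with 4482 called once each library's length trend was removed. With the sums of the on/off sets as covariates 5125 were called. No gene of these sets was among the 4432, and no set sum differed between the 4 ages in the permutation tests. A large fall was therefore unlikely from the start, and the count of 5125 decides little. Chance in how the 10 libraries fell into the ages could be excluded, as far as 100 splits can show. Only the real split gave as many genes, 1 of 100, and the highest other gave 1. This takes the libraries as independent, and the labels do not say whether they came from separate fish. Age stays an open explanation that may account for the difference, and so does any handling shared by the libraries of an age, which the labels do not give and which cannot be told apart from age.

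Over the other comparisons, the same limit on independent libraries holds. Chance could be excluded for the 265 genes between 7 and 5 weeks as counted over all libraries (1 of 100 splits as large, highest other 1). Leaving out 1 library gave 19 or more. With 5 weeks replicates 4 and 5 left out 2 genes were called, and without the 9 libraries with a set over 1000 CPM 1 was, so this exclusion does not extend to those settings, for which no splits were run. For the 5000 genes over 4 ages 1 of 100 splits, the real one, was as large. Without 7 weeks replicate 2 the count was 3082, a fit on fewer libraries that the splits do not match. The highest other split gave 4424 genes, not far under 5000, so chance was not firmly excluded. For the trend, 1306 genes, 4 of 100 splits were as large, 1 under the 5 set as the limit. The highest other gave 3908 and leaving out 1 library gave 7 to 2867, so it was not firmly excluded there either. It could not be excluded for the 2 genes between 14 and 5 weeks, as many as which came from 8 of 100 splits, with a highest of 2681. For the 0 genes between 14 and 10 weeks the count of splits says nothing, since 100 of 100 reach 0 by construction. There the highest other gave 6835 and 14 splits called genes where the real one called none, which points to a structure of the libraries other than these 2 ages.

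The RPKM values followed the formula with depths running down the rows in 99.9992% of cases and that with each library's own depth in 4.60%. Lengths came from the first formula, so the second share decides nothing. The ratio of counts to RPKM between 2 libraries, free of length, followed a repeat of 25 rows (1.8e-07 of its log2 variance left). Own depths would keep that ratio constant, so this argues against them. A misplaced division by a vector of library totals is a candidate explanation, found and tested on the same table. The 5 depths that match no library analysed here may belong to libraries not analysed here.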

How the results depend on the processing

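Alternatives named in the methods as chosen after the data were seen are so here too, and causes were not tested unless given. The 45 gene lists and their alternatives, and named genes with symbols, were not run, since no ID had a name. No paired analysis was possible because the replicate numbers follow accession order. The count between 10 and 7 weeks stayed within 1.5 times of 4432 in 15 of 16 settings and without any single library (3212 to 4784), the exception being the RPKM table as deposited, with 1763. On those values limma called 871 genes over 4 ages, 4 between 7 and 5 weeks and 3 for the trend. With each library's own depth these were 2790, 14 and 4, and the median log2 change between 10 and 7 weeks was −0.116, against −0.065 as deposited and −0.009 in edgeR. DESeq2 called 7563 genes over 4 ages, 2305 between 14 and 5, 1121 between 7 and 5 and 244 between 14 and 10 weeks, and 3191 for the trend. limma voom called 0 between 14 and 5 weeks and 522 for the trend. Between 14 and 5 weeks 0 were called with the strict filter, which removed both genes, and 0 with only the 2 ages fitted. Without the 9 libraries with an on/off set over 1000 CPM, 2509 were called between 14 and 5, 1 between 7 and 5 weeks and 3358 for the trend. With set sums as covariates these were 5, 540 and 14, and with 5 weeks replicates 4 and 5 left out 1478, 2 and 3816. Leaving out 1 library gave 3082 to 6931 genes over 4 ages, 0 to 2141 between 14 and 5, 19 to 323 between 7 and 5 and 0 to 514 between 14 and 10 weeks, and 7 to 2867 for the trend. Between 7 and 5 weeks it gave 66, 31 and 44 without 5 weeks replicate 3, 4 and 5, 51, 27, 160 and 19 without 7 weeks replicate 1, 2, 3 and 4, and 173 without 10 weeks replicate 5. For the trend it gave 7, 11, 14, 2281 and 2107 without 5 weeks replicate 1 to 5, 16, 555, 2161 and 155 without 7 weeks replicate 1 to 4, 760 and 856 without 10 weeks replicate 3 and 5, and 2867, 9 and 9 without 14 weeks replicate 2, 3 and 4. The larger spread at 14 weeks passed the exact test in every setting but that without the 9 libraries, where the difference was 0.0285 and p = 0.1, the smallest that 2 against 3 libraries allow. Both genes lower at 14 than at 5 weeks kept their sign in all 35 alternatives, with an adjusted p over 0.05 in 4 and 5 of them (highest 0.209, edgeR on the 2 ages alone). Nfu_g_1_001708 passed in 36 of 36 and Nfu_g_1_001750 in 35 of 35, since DESeq2 gave it no adjusted p. With 200 changed genes in simulated data, 9% to 25% of 2-fold changes were recovered, which is no limit where more genes change. The simulation had this depth but the same dispersion at all ages and independent genes, so the shares may be too high.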

Other observations

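Nfu_g_1_001708 stood at 165 CPM in 5 weeks replicate 4 and at 1.24 CPM in the lowest 5 weeks library, against 71.7 to 415 CPM at 10 weeks. Genes longer than most were called between 7 and 5 weeks, with a median of 4477 bases for those higher and 3026 bases for those lower at 7 weeks, against 2604 bases for all tested genes with a length (96.9% of tested genes). Between 10 and 7 weeks the medians were 2771 and 2778 bases. The share of counts taken by the 20 most counted genes was 30 ± 2.8% (SD, n = 5) at 5 weeks and 21.1 ± 6.1% (SD, n = 5) at 14 weeks, and was lowest in 14 weeks replicate 4, at 13.6%.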
